A study of Rattus norvegicus with 6 samples.

How the data were processed

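RNA was measured in 6 samples of rat Leydig cells, the testosterone-producing cells that lie between the seminiferous tubules of the testis. Per the labels, the cells were primary cells of Sprague-Dawley rats kept in medium with 10% fetal bovine serum at 34 °C under 5% CO2. In 3 samples the medium also received exosomes, small membrane vesicles, released by primary rat Sertoli cells, at 5 µg/ml for 24 h. The other 3 samples received none and are called untreated here. The labels name total RNA, TRIzol extraction, linear amplification and Cy3 labelling for 1-colour Agilent arrays. They number the replicates 1 to 3 in both groups but do not say whether these came from separate animals or cultures, so the p-values measure only the spread between these samples.

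Each array file held, per the file headers, fluorescence intensities of 44254 spots read with Agilent Feature Extraction 11.0.1.1. Of these spots 1377 were controls and 42877 were gene spots, which held 30367 probes, 1390 of them spotted 10 times. The signal used was the processed intensity, which per the file headers is corrected for background and spatial trend within an array and not normalized between arrays. The table of all samples that the authors deposited holds log2 values. Its 6 columns share 1 median of 5.68 and 1 maximum of 17.0, and each correlated with the log2 intensity of its own array at r of 0.996 or above, so it was treated as quantile normalized. It served as an alternative only.

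Gene symbols came from the RefSeq accession that the files give for a probe, looked up in a table of RefSeq genes of rat assembly GRCr8, used for names only because the array was designed on build rn4. A symbol was found for 18005 probes, covering 15168 genes, and 12362 probes without one entered the counts of probes only. No positions are given for this reason.

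Processing used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and R 4.3.3 with limma 3.58.1. Figures were drawn with matplotlib 3.10.9. Spots with a non-uniformity or population outlier mark, between 388 and 572 per array, were left out, and spots of 1 probe were averaged on the log2 scale. From each array its 75th percentile was subtracted, so that 0 stands for that percentile. A probe was tested if it was well above background on at least 3 of the 6 arrays, in whichever group, which kept 20435 probes (67.3%) and 10981 genes. A gene was represented by the tested probe of highest mean signal. limma fitted 1 model with the 2 groups, the spread of each probe was moderated over all probes (prior degrees of freedom 2.60), and p-values were adjusted by Benjamini-Hochberg over all tested probes. A probe is called past the test at an adjusted p below 0.05. Fold changes are log2 differences, exosome minus untreated, with their standard error (SE).

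The number of arrays limits the precision. The procedure was tested on simulated data made from 20418 probes for this comparison: of 50 changed probes each, it recovered 2% at 1.5-fold, 56% at 2-fold, 94% at 4-fold and 100% at 8-fold, and 13 of its 139 calls were unchanged probes. Only these probes were changed, whereas 42.4% of tested probes passed the test in the real data, and no slide effect was simulated. The rates hold for that simulated setting and do not give the sensitivity of the real comparison. Where a gene was well above background on no array of 1 group, a bound is given as "at least N-fold". It was computed by raising each value of that group to at least the dimmest value that counted as well above background on the same array, and then taking the difference of group means, and it holds for the 75th percentile scaling only.

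The test, the filter, 27 gene lists, the rule for named genes and the alternatives listed at the end were fixed before the data were examined. The lists cover pathways and markers of cell types that a Leydig cell preparation could hold, 14 of the tested genes stand in 2 lists, and each list with at least 5 tested genes was tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists. The rule names the 8 largest rises and the 8 largest falls among genes past the test whose arrays do not overlap between groups, 10 genes of steroid synthesis and Leydig cell identity and of the chemokine Ccl20 whatever their values, the 2 to 4 members of smallest p of each list with a member past the test, and all such members where a list had 5 or fewer. Genes named outside it were chosen after their values were seen, and this is said where they appear. So were 40 families of genes read from their symbols, each with at least 10 tested genes, and the comparison of probes of 1 gene. A few of the genes picked by the rule or later are not reported here and stay in the counts.

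Alternatives changed 1 choice at a time, except normexp, which also changed the intensity, and the 2-fold minimum, tried at both adjusted and unadjusted p. They were a normexp background correction with an offset of 50, quantile normalization, centring on the median of tested probes, the authors' table, no filter, a filter on all 6 arrays, outlier spots kept, a trended and robust moderation, array weights, the replicate number as a block, the slide as a random block, the mean of a gene's probes, a 2-fold minimum, each array left out in turn, camera with an estimated correlation, and fry. The normexp correction used the median intensity of each spot in place of the mean, which the array files used here do not hold. Intervals for medians and correlations over genes are 95% bootstrap intervals from 2000 draws. The file headers put the 3 untreated arrays on 1 slide, exosome 1 and exosome 2 on another and exosome 3 on a slide of its own. Each slide therefore held arrays of 1 group only, and slide and treatment cannot be told apart. Spike-in and other control spots were left out of every comparison except where control probes are named.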

Results

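The series compared primary rat Leydig cells kept for 24 h with exosomes released by Sertoli cells, the nurse cells of the seminiferous tubule, with Leydig cells that received none. It asks which transcripts of Leydig cells differ after they have met vesicles from their neighbours. Each group had 3 samples, each read on 1 array. On the untreated arrays 72.6%, 75.6% and 74.6% of gene spots were well above background, and on the exosome arrays 72.2%, 69.1% and 67.2%. No spot was saturated. The 75th percentile of the processed intensity was 872, 779 and 753 on the untreated arrays and 1004, 1061 and 860 on the exosome arrays. Arrays of 1 group correlated at r of 0.984 to 0.994 over tested probes (6 pairs) and arrays of different groups at 0.969 to 0.983 (9 pairs), and the first principal component, with 59.5% of the variance, separated the groups. Fold changes below are log2 differences, exosome minus untreated, ± SE with n = 3 per group, and adjusted p-values are from limma with Benjamini-Hochberg.

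Exosome-treated cells held less mRNA of some steroid enzymes and more of some inflammatory mediators, although neither list passed camera as a whole. Inflammation genes moved both ways (8 rose and 10 fell). Of 18 steroid synthesis genes 5 fell, no larger a share than that of all genes (3209 of 10981). Star and Hsd3b1, also of steroid synthesis, missed the test (−0.26 and 0.17). Cyp11a1, which catalyses the first step from cholesterol to steroids, fell by 0.86 (SE 0.12, adjusted p = 0.0098), and Gata4, a transcription factor of Leydig and Sertoli cells, fell by 1.61 (SE 0.24, adjusted p = 0.010). Il1b, an inflammatory cytokine above background on 3 exosome arrays and 0 untreated ones, rose by at least 4.46-fold (adjusted p = 0.011), though under the normexp correction, whose offset shrinks changes of dim genes, its log2 change was 0.46. The granulocyte growth factor Csf3 rose by 2.31 ± 0.51 (adjusted p = 0.016), and the chemokines Cxcl2 and Ccl2, which attract neutrophils and monocytes, rose by 1.27 ± 0.25 and 0.91 ± 0.17. Idi1, an enzyme of cholesterol synthesis, rose by 1.34 ± 0.22 (adjusted p = 0.011). Cyp11a1, Gata4, Il1b, Csf3, Cxcl2, Ccl2 and Idi1 each had all 3 arrays of 1 group above all 3 of the other. So did 62.0% of all tested genes. Cyp11a1, Gata4, Il1b and Idi1 stayed past the test whichever array was left out, while Csf3, Cxcl2 and Ccl2 missed it without untreated 2 (2.21, 1.21 and 0.93) and without untreated 3 (2.10, 1.11 and 0.89).

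**Figure D1:**
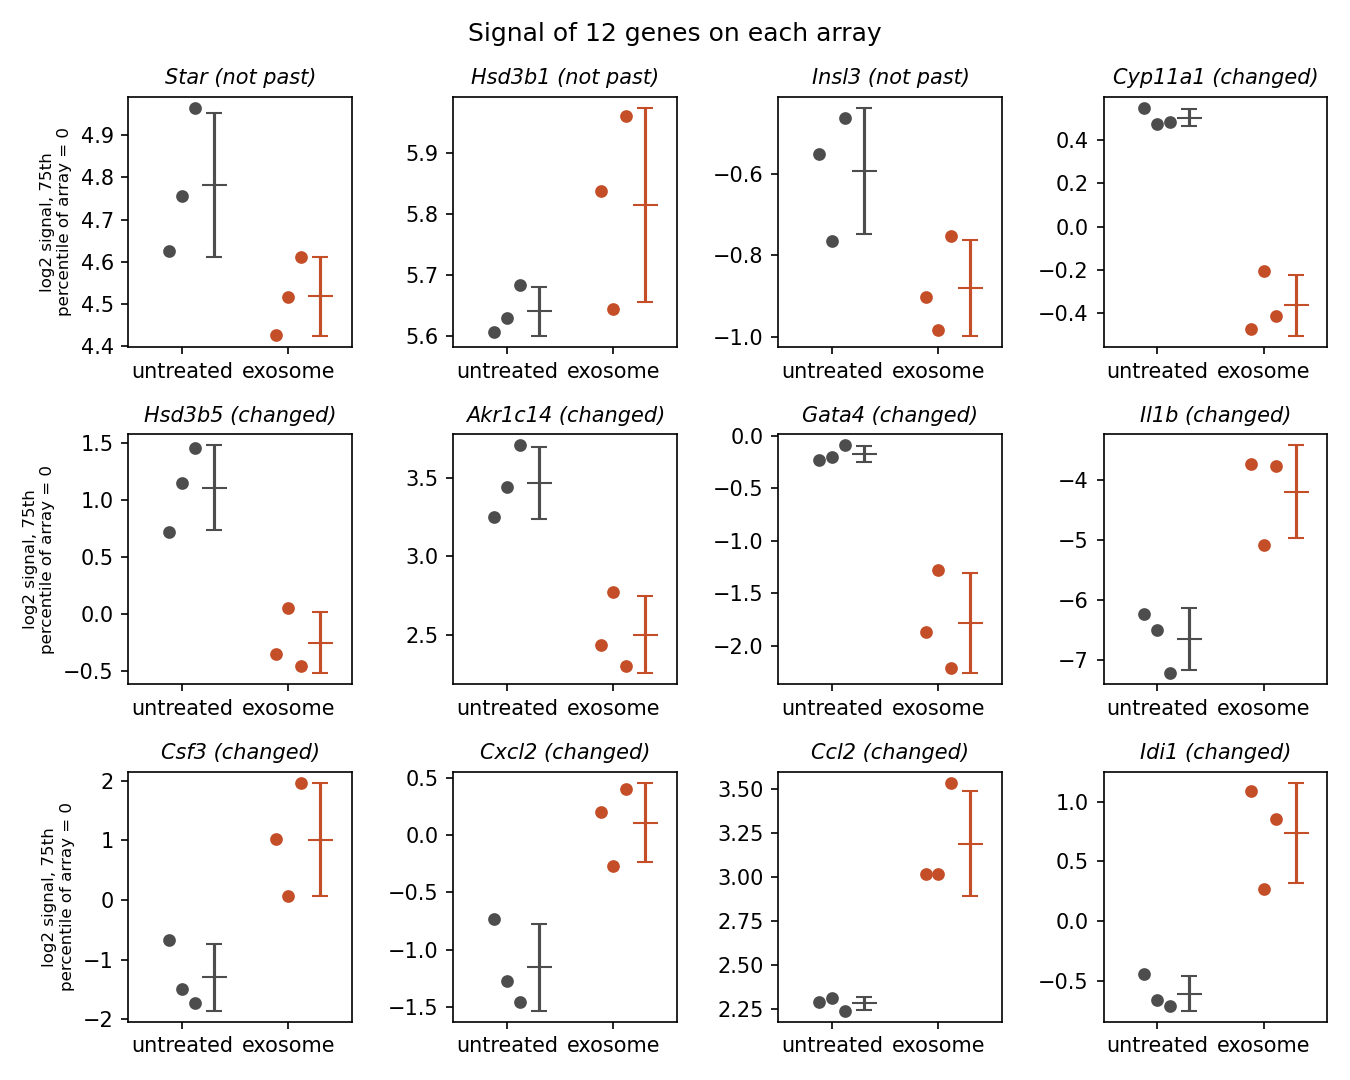
Normalized log2 signal of 12 genes on each array, with the 75th percentile of the array set to 0; points are arrays, and the bar beside each group is the mean ± SD (n = 3). Cyp11a1 lies near 0.50 on the untreated arrays and near −0.36 on the exosome arrays, while the signals of Hsd3b1 overlap between the groups.

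Of 10981 genes tested, 1598 were higher and 3209 lower in exosome-treated cells. Both counts depended on single arrays: without untreated 2 they were 134 and 820, without untreated 3 they were 214 and 1002, without exosome 1 they were 377 and 1406, and without exosome 3 the genes higher numbered 767. The balance between the directions depended on the scaling, since the median change of all genes was −0.19 and moved to 0.01 under quantile normalization, which gave 2214 higher and 1766 lower. The authors' table gave 2217 and 1783, centring on the median 2756 and 1856, and the normexp correction 1965 and 3880. Of the 4807 genes past the test, 4766 kept their direction in all 5 scalings, and 1407 genes rose and 1335 fell past the test in all 5. The arrays of the groups did not overlap for 6812 genes (62.0%), where chance gives 10% if arrays are exchangeable. Slide was confounded with group and the median was shifted, so the excess cannot be put down to exosomes alone. At 2-fold or more, 163 genes were higher and 888 lower. Probes of 1 gene often moved apart. In 265 genes with 2 tested probes both were past the test, and 143 pairs went the same way and 122 opposite ways. A value given for a gene is therefore that of its brightest probe and may not hold for another probe of the gene. Cyp11a1, Gata4, Il1b, Csf3, Cxcl2, Ccl2 and Idi1 had 1 tested probe each, so no second probe could check their changes.

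**Figure D2:**
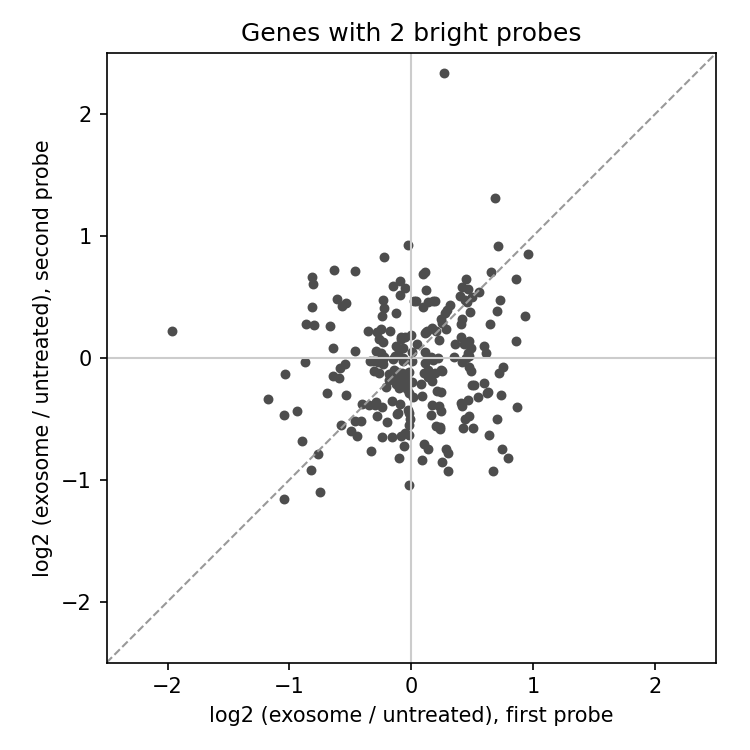
Log2 fold change, exosome over untreated, of both probes of each of 230 genes with a pair of bright probes; points are genes and the dashed line is equality. The points scatter around 0 with r = 0.118 across genes.

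The 8 largest rises by fitted value included Or51s1, an olfactory receptor gene (at least 3.27-fold), and Golt1a, a Golgi transport gene (3.09 ± 0.63, above background on 1 untreated array). Mmp28, a matrix metalloproteinase, rose by at least 4.04-fold. Pkib, an inhibitor of protein kinase A, rose by 2.43 ± 0.62, and Il1b and Csf3 are described above. Gxylt1, which adds xylose to Notch receptors, rose by 2.37 ± 0.52, and Nus1, a subunit of the enzyme that makes dolichol, by 2.23 ± 0.47. In both genes the other tested probe also rose past the test. The fitted values of Or51s1, Mmp28 and Golt1a shrank to 0.41, 0.34 and 0.73 under the normexp correction. Or51s1 and Mmp28 stayed past the test whichever array was left out. Golt1a, Pkib, Gxylt1 and Nus1 missed it without untreated 2, with values of 3.21, 2.34, 2.39 and 2.18. Pkib, Gxylt1, Csf3 and Nus1 spread widely among the exosome arrays, with SDs of 0.83 to 1.13 against a median of 0.19 over genes.

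The 8 largest falls were mostly of dim genes. Myh14, a non-muscle myosin, fell at least 3.43-fold, Neto1, an accessory protein of glutamate receptors, at least 3.18-fold, and Ptprz1, a receptor phosphatase, at least 2.27-fold. The olfactory receptor genes Or6b6, Or6c202e and Or1i2 fell at least 2.59-fold, 2.79-fold and 2.12-fold. Glyatl2, which joins glycine to acyl groups, fell by 2.84 (SE 0.71), and the olfactory receptor gene Or13a27d by 2.64 (SE 0.46); each was above background on 1 exosome array. The fitted values of these genes shrank in the same way, to −0.87 for Myh14 and −0.82 for Or6b6. Or6c202e and Glyatl2 missed the test without untreated 2, with values of −2.88 and −2.50.

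Among genes well above background on all arrays, with 1 direction in the 5 scalings, a further set was chosen after the values were seen. It added rises of Pax3, a developmental transcription factor (1.95 ± 0.41), Bclaf1, a nuclear protein linked to RNA processing (1.90 ± 0.32), Hivep3, a zinc finger protein (1.84 ± 0.48), and Tcf15, a developmental transcription factor (1.76 ± 0.37). The falls were those of Glra2, a glycine receptor subunit (−2.02 ± 0.41), Ptprn2, a phosphatase-like protein of secretory granules (−2.02 ± 0.42), Cym, the protease chymosin (−2.01 ± 0.42), Extl3, which builds heparan sulfate (−2.01 ± 0.41), Cx3cr1, the fractalkine receptor of macrophages (−1.94 ± 0.40), Ano7 (−1.84 ± 0.42), Tmem47 (−1.84 ± 0.42) and Cyp2e1, a xenobiotic-metabolizing enzyme (−1.80 ± 0.24). Bclaf1 and Cyp2e1 alone among these 12 stayed past the test in every fit that left out an array. Without untreated 2 the values of Pax3 and Glra2 were 1.92 and −1.92. Glra2, Ptprn2, Cym, Extl3, Cx3cr1 and Tmem47 spread widely among the untreated arrays, with SDs of 0.82 to 0.86. The median SD over genes was 0.16, while Cyp2e1 had 0.34 and Ano7 0.10. The falls of these widely spread genes were alike in size, and whether they are independent was not tested.

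Steroid synthesis genes fell or missed the test. Of 18 measured, 0 rose and 5 fell, and 5 were also past the test when adjusted over the list alone. This share is no larger than that of all genes (3209 of 10981 fell). Camera gave the list an adjusted p of 0.753. Besides Cyp11a1 these were Hsd3b5, a 3-beta-hydroxysteroid dehydrogenase (−1.36 ± 0.23), Akr1c14, which reduces 3-ketosteroids (−0.96 ± 0.18), Srd5a1, a steroid 5-alpha-reductase (−1.02 ± 0.23), and Por, which passes electrons to microsomal P450 enzymes (−0.67 ± 0.11). Srd5a1 and Por missed the test under quantile normalization (−0.65 and −0.26) and in the authors' table. Akr1c14 missed it without untreated 2 (−0.98), and Srd5a1 without untreated 3 (−1.08) and without exosome 1 (−0.93). Star, the carrier that brings cholesterol into mitochondria, had a change of −0.26 ± 0.13 (adjusted p = 0.149), Hsd3b1 one of 0.17 ± 0.13 (adjusted p = 0.291) and Cyp17a1 one of −0.30 ± 0.23 (adjusted p = 0.313), whose sign was positive under quantile normalization (0.20) and in the authors' table. Hsd17b3, the testicular enzyme of the last step to testosterone, was above background on 1 array and was not tested.

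Of 14 measured Leydig cell genes, 3 rose and 4 fell, the same counts as when adjusted over the list alone; quantile normalization gave 4 and 3. Vcam1, an adhesion molecule, rose by 0.85 ± 0.13, and Nr4a1, a nuclear receptor that drives steroid genes, by 0.60 ± 0.11. Gata4 was among those that fell. Insl3, the hormone most specific to Leydig cells in the testis, had a change of −0.29 ± 0.13 (adjusted p = 0.123). Lhcgr, the receptor of luteinizing hormone, and Nr5a1, the steroidogenic transcription factor, were above background on 0 of the 6 arrays. Vcam1 and Gata4 stayed past the test whichever array was left out, and Nr4a1 missed it without untreated 2 (0.60).

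Chemokine genes had the smallest camera p of the 27 lists at the preset correlation, though not with an estimated one or in fry. Of 23 measured, 6 rose and 2 fell, and adjusted over the list alone the counts were 6 and 1. Beside Cxcl2 and Ccl2, Cxcl1, which attracts neutrophils, rose by 0.72 ± 0.15, and Cxcl14 by 0.69 ± 0.15, while Ccl7, a monocyte chemokine named after its value was seen, fell by 0.51 (SE 0.16). Ccl20 had a change of 0.41 ± 0.41 (adjusted p = 0.445), while its other tested probe rose past the test, and its receptor Ccr6 was above background on 1 array. Camera gave p = 0.0078 and adjusted p = 0.211 for the list, and p = 0.245 with an estimated correlation. Of the markers of macrophages, which also make chemokines, 3 rose and 8 fell, but 7 rose and 4 fell under quantile normalization. Cxcl1 and Cxcl14 missed the test without untreated 2, with values of 0.76 and 0.68. Without untreated 2 and without untreated 3, 0 of the list rose. Ccl7 missed it in 9 alternatives, among them median centring (−0.28), no filter, both blocks and 5 of the 6 fits that left out an array.

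Genes of NF-kB signalling and inflammation moved both ways. Of 29 measured, 8 rose and 10 fell (10 and 11 adjusted over the list alone), and quantile normalization gave 12 and 6. Without untreated 2 there were 2 and 1, and without exosome 3 there were 3 and 4. Il1b, Csf3, Vcam1 and Bcl3, a nuclear partner of NF-kB (0.96 ± 0.24), rose. Lcn2, an iron-binding protein of the acute phase, fell by 0.96 (SE 0.16), Mmp3, a matrix protease, by 1.08 (SE 0.22), C3, the central complement protein, by 0.73 (SE 0.20), and Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, by 0.68 (SE 0.20). Bcl3, C3 and Nfkbia were named after their values were seen, and all 3 missed the test without untreated 2 (0.93, −0.80 and −0.65). Of 36 interferon-response genes 6 rose and 7 fell, as when adjusted over the list alone, and quantile normalization gave 11 and 6. Tap1, which loads peptides onto class I molecules, fell by 1.19 (SE 0.19) and Ifi47 by 0.94 (SE 0.19), while the antiviral genes Mx2 and Ifi44 rose by 0.90 ± 0.18 and 0.81 ± 0.15.

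Of 24 cholesterol synthesis and transport genes, 7 rose and 2 fell (6 and 2 adjusted over the list alone). Idi1 rose most, followed by Stard4, a sterol carrier (0.77 ± 0.14), Sqle, which makes squalene epoxide (0.64 ± 0.14), and Tm7sf2, a sterol reductase (0.61 ± 0.13). Mvk, an early kinase of the same pathway, fell by 0.92 (SE 0.16), and Nsdhl, a late demethylation enzyme, by 1.09 (SE 0.24). Sqle and Nsdhl were named after their values were seen. Camera gave p = 0.022 and adjusted p = 0.236 for this list, and p = 0.074 with an estimated correlation. The second probe of Stard4 did not move with the first, and Mvk, Stard4, Tm7sf2, Sqle and Nsdhl missed the test without untreated 2 (−0.90, 0.75, 0.61, 0.62 and −1.08). Of 26 fatty acid and lipid genes 3 rose and 8 fell, as when adjusted over the list alone. The elongase gene Elovl6 rose by at least 2.20-fold, but this bound equals its fitted change and leaves no margin. The call was lost under the normexp correction (0.03, adjusted p = 0.823). The fatty acid receptor Cd36 rose by 0.86 ± 0.17. Fabp3, a fatty acid carrier, and Hadha, an enzyme of beta-oxidation, fell by 0.85 (SE 0.18) and 0.83 (SE 0.17).

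**Figure D3:**
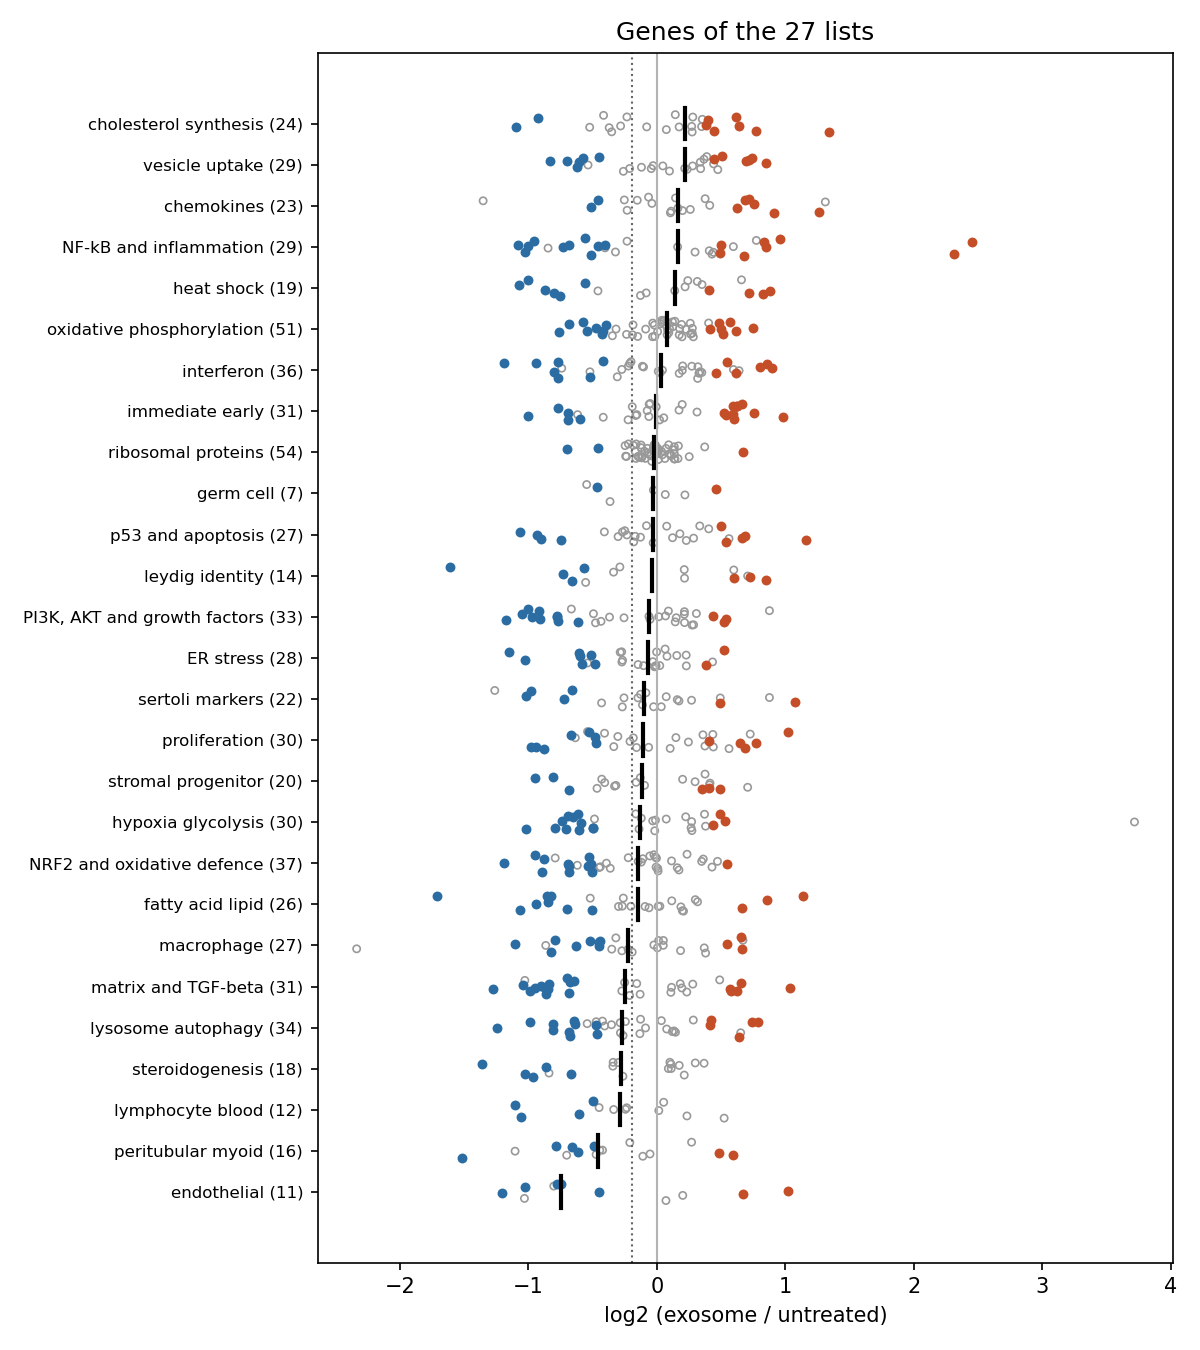
Log2 fold change, exosome over untreated, of each tested member of the 27 gene lists, with the number tested in brackets; filled points passed the test, black bars are list medians, and the dotted line is the median of all genes at −0.19. The endothelial and peritubular myoid lists have the lowest medians, at −0.74 and −0.46.

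In 5 of the 7 lists of markers of other testis cells more genes fell than rose, as among all genes past the test, of which 66.8% were lower, and no list passed camera. The balance turned under quantile normalization for the macrophage, Sertoli cell and lymphocyte lists and was even for the endothelial list (2 and 2). Of 16 genes of peritubular myoid cells, the contractile cells around the tubules, 2 rose and 5 fell (2 and 6 adjusted over the list alone), among them Hspb6 (−1.51 ± 0.19), Tagln (−0.66 ± 0.12) and Myl9 (−0.49 ± 0.12), while Mylk rose by 0.59 ± 0.15. Of 11 endothelial genes 2 rose and 5 fell (2 and 6 adjusted over the list alone), with falls of Esam, Sox18 and Eng (−1.21 ± 0.24, −1.02 ± 0.12 and −0.78 ± 0.15) and a rise of Pecam1 (1.02 ± 0.19). Eng missed the test under quantile normalization (−0.39, adjusted p = 0.113) and in the authors' table. Of 27 macrophage genes 3 rose and 8 fell, as when adjusted over the list alone, with falls of Cd74 (−1.10 ± 0.23), C1qc (−0.82 ± 0.15) and C1qa (−0.63 ± 0.13) and a rise of Cd53 (0.66 ± 0.15), and quantile normalization gave 7 and 4. Of 22 Sertoli cell genes 2 rose and 4 fell (1 and 4 adjusted over the list alone), with quantile counts of 3 and 1. They included Clu, the chaperone clusterin (−1.02 ± 0.18), Cst12 (−0.98 ± 0.20, above background on 1 exosome array), Gstm6l (−0.72 ± 0.16) and Nr0b1 (−0.66 ± 0.18). Cd74, Cst12, Gstm6l and Nr0b1 missed the test under quantile normalization (−0.67, −0.37, −0.34 and −0.25). Hspb6, Tagln, Sox18 and Clu stayed past the test whichever array was left out, and without untreated 2 Mylk and C1qc missed it (0.59 and −0.85).

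Of 20 stromal progenitor genes 3 rose and 3 fell (1 and 3 adjusted over the list alone), with falls of Igfbp6 (−0.95 ± 0.12), Gsn (−0.81 ± 0.17) and Osr1 (−0.69 ± 0.18) and a rise of the growth factor receptor gene Pdgfra (0.49 ± 0.11). Of 12 lymphocyte and blood genes 0 rose and 4 fell, 3 of them also past the test when adjusted over the list alone. These were Cpa3, a mast cell protease (at least 1.77-fold), the T cell genes Cd8a (−1.06 ± 0.30) and Cd3d (−0.50 ± 0.13), and Alas2, an enzyme of heme synthesis in red cells (−0.61 ± 0.10), and none of the 4 stayed past the test under quantile normalization, where 3 other members rose and 0 fell. Of 7 germ cell genes, Odf2, of the sperm tail, rose by 0.46 ± 0.12 and Prm2, of sperm chromatin, fell by 0.46 (SE 0.14), and 0 were past the test when adjusted over the list alone. Prm2 had a positive sign under quantile normalization (0.02) and in the authors' table (0.01). Without untreated 2, Igfbp6 stayed past the test at −0.99, while Pdgfra and Odf2 missed it at 0.49 and 0.44.

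Stress and heat shock genes moved both ways. Of 19 heat shock genes 4 rose and 6 fell (4 and 7 adjusted over the list alone): the small heat shock genes Hspb1 and Hspb8 fell by 1.07 (SE 0.11) and 0.87 (SE 0.14) and Fkbp4, a partner of steroid receptors, by 0.76 (SE 0.14), while Hspa4 rose by 0.83 ± 0.15. Of 28 genes of endoplasmic reticulum stress 2 rose and 7 fell (1 and 6 adjusted over the list alone). Sesn2 fell at least 1.98-fold (log2 change −0.57 under quantile normalization and −0.41 under normexp, below that bound), Asns, which makes asparagine, by 1.03 (SE 0.19) and Trib3 by 0.58 (SE 0.14), while Atf3 rose by 0.52 ± 0.12, and quantile normalization gave 4 and 3. Of 37 genes of oxidative defence 1 rose and 11 fell, as when adjusted over the list alone. Of the falls 3 held in all 5 scalings, and without exosome 3 the counts were 0 and 5. Among the genes that fell were Txnrd1, Akr1b8, Gstm1 and Gstp1 (−0.95 ± 0.21, −0.89 ± 0.17, −0.87 ± 0.15 and −0.51 ± 0.12). Of 27 genes of p53 and apoptosis 5 rose and 4 fell (3 and 4 adjusted over the list alone), with Phlda3, Casp9 and the cell cycle inhibitor Cdkn1a at −1.07 ± 0.21, −0.90 ± 0.17 and −0.75 ± 0.11 and Zmat3 at 1.16 ± 0.20. Hspb1, Hspb8, Sesn2, Gstm1, Cdkn1a and Zmat3 stayed past the test whichever array was left out, and Asns missed it without untreated 2 (−1.03).

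Genes of energy metabolism were split. Of 30 hypoxia and glycolysis genes 3 rose and 11 fell (3 and 12 adjusted over the list alone), among them the glycolytic enzymes Eno1, Aldoa and Gapdh (−0.79 ± 0.14, −0.65 ± 0.13 and −0.61 ± 0.13) and the regulator Pfkfb3 (−0.74 ± 0.13). Of 51 genes of oxidative phosphorylation 7 rose and 8 fell (5 and 6 adjusted over the list alone), with Cox6b1, Atp5f1c and Ndufs7 at −0.76 ± 0.17, −0.68 ± 0.15 and −0.57 ± 0.12 and Ndufa5 at 0.75 ± 0.16. Of 54 ribosomal protein genes 1 rose and 2 fell (0 and 1 adjusted over the list alone), namely Rpl15 (0.67 ± 0.15), Rps26 (−0.70 ± 0.11) and Rps25 (−0.46 ± 0.13). Eno1 and Rps26 stayed past the test whichever array was left out, while Aldoa and Gapdh missed it without untreated 2 (−0.69 and −0.62). The oxidative phosphorylation list had camera p = 0.038 and adjusted p = 0.236, with p = 0.552 under an estimated correlation.

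Of 31 immediate early genes, which respond fastest to a stimulus, 10 rose and 5 fell, as when adjusted over the list alone. Egr2, Dusp6 and Nr4a1 rose by 0.98 ± 0.13, 0.63 ± 0.12 and 0.60 ± 0.11, and the clock gene Per1 fell 2.01-fold (adjusted p = 0.012). Of 33 genes of growth factor and PI3K signalling 3 rose and 10 fell, as when adjusted over the list alone, with Hbegf, Insr, Igf1r and Fgfr1 at −1.17 ± 0.21, −1.05 ± 0.17, −0.78 ± 0.15 and −0.77 ± 0.11, Insr above background on 1 exosome array. Quantile normalization gave 7 and 4, and Insr and Igf1r missed the test there (−0.49 and −0.34) and in the authors' table. Of 30 proliferation genes 5 rose and 7 fell (5 and 6 adjusted over the list alone), with Rrm2, Ccna2 and Ccne1 at 1.02 ± 0.16, 0.69 ± 0.17 and 0.65 ± 0.15 and the replication helicase gene Mcm2 at −0.94 ± 0.18. The quantile counts were 8 and 3, and the second probe of Rrm2 did not move with the first. Egr2, Hbegf, Fgfr1 and Rrm2 stayed past the test whichever array was left out, and without untreated 2 Dusp6 and Per1 missed it (0.62 and −1.02). Camera gave the immediate early list p = 0.044 and adjusted p = 0.236, with p = 0.140 under an estimated correlation.

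Genes of vesicle uptake and release were also split, with 6 of 29 higher and 6 lower, as when adjusted over the list alone, and 10 and 5 under quantile normalization. Rab27a, which docks vesicles for secretion, rose by 0.69 ± 0.14, while Cd81, a tetraspanin found on exosomes, fell by 0.83 (SE 0.16) and the sorting genes Vps28 and Vps4a by 0.70 (SE 0.13) and 0.58 (SE 0.12). The list had camera p = 0.042 and adjusted p = 0.236, with p = 0.082 under an estimated correlation. Of 34 lysosome and autophagy genes 5 rose and 10 fell (6 and 11 adjusted over the list alone), with Lamp1, Tfeb and Wipi1 at −0.98 ± 0.20, −0.81 ± 0.12 and −0.81 ± 0.14 and the protease gene Ctsk at 0.78 ± 0.15; quantile normalization gave 6 and 5. Of 31 matrix and TGF-beta genes 5 rose and 13 fell (6 and 14 adjusted over the list alone), with Timp3, Tgfb3 and Tgfbi at −1.04 ± 0.15, −0.99 ± 0.19 and −0.67 ± 0.13 and Ccn1 at 1.03 ± 0.21. Timp3 and Ccn1 stayed past the test whichever array was left out, and without untreated 2 Rab27a, Cd81 and Lamp1 missed it (0.69, −0.83 and −1.02).

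The counts of list members that rose or fell depended on single arrays. Of the 54 counts, 50 moved by more than 1.5 times without untreated 2, 49 without untreated 3, 44 without exosome 1 and 26 without exosome 3. As whole lists, 0 of 27 passed camera, which compares a list with all other genes; 5 had an unadjusted p below 0.05, and with an estimated correlation 0 passed, the smallest p being 0.074. Using the mean of a gene's probes, 1 list passed, the chemokines. fry, which tests whether a list moves one way on balance without comparing it with other genes, called 10 lists. Lower were peritubular myoid, endothelial, lysosome, endoplasmic reticulum stress, glycolysis, steroid synthesis, growth factor and oxidative defence genes (adjusted p from 0.0043 to 0.049), and higher were cholesterol synthesis and vesicle genes (both adjusted p = 0.042). Its mixed test, for change in either direction, called all 27. Because camera compares with other genes, whose median was −0.19, the ribosomal, proliferation, Leydig, stromal, Sertoli, germ cell and fatty acid lists pointed upwards in it although their median and mean were below 0. The median and mean also differed in sign for immediate early (−0.00 and 0.05), interferon (0.03 and −0.00), p53 (−0.03 and 0.00) and heat shock genes (0.14 and −0.05). Under quantile normalization the medians of the immediate early, p53, ribosomal, proliferation, lymphocyte, Leydig, stromal, growth factor, Sertoli, germ cell and fatty acid lists turned positive.

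**Figure D4:**
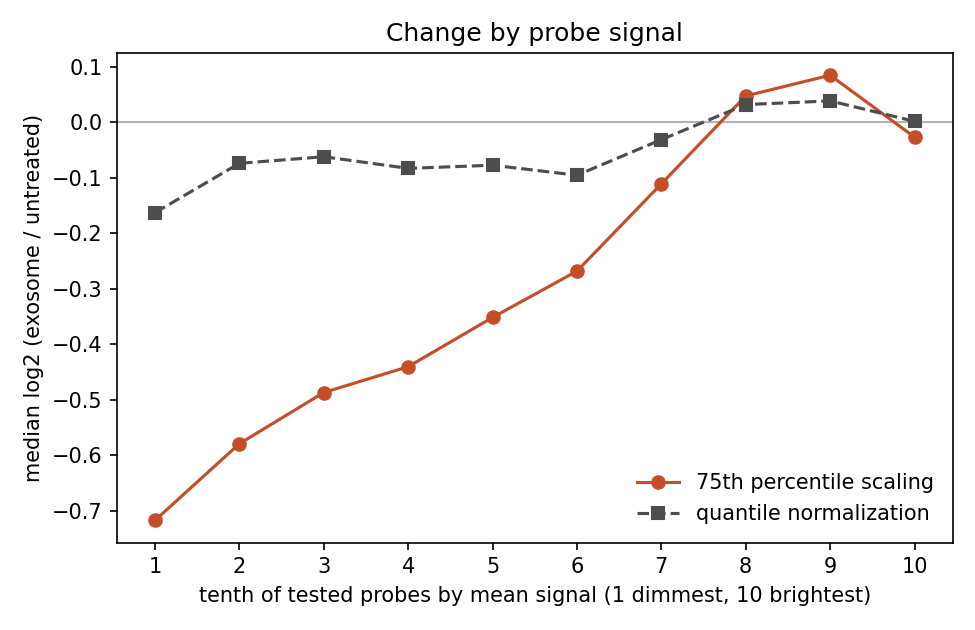
Median log2 fold change, exosome over untreated, of tested probes in 10 bins of mean signal from dimmest to brightest, under the 75th percentile scaling (circles) and quantile normalization (squares). The dimmest bin lies at −0.72 and −0.16 and the brightest at −0.03 and 0.00.

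Dim probes were lower than bright ones in the exosome group. With tested probes in 10 bins of signal, 37.9% of the dimmest bin fell and 1.52% rose past the test, and of the brightest bin 10.3% fell and 10.4% rose. Of the 144 named genes past the test, 118 stayed past it in all scalings (besides genes marked above, Trib3, Tfeb and Rps25 missed it under quantile normalization, and Gstp1, Ndufs7, Myl9, Osr1, C3 and Nfkbia with median centring), 138 with the slide as a random block and 45 whichever array was left out. The other 99 missed it in at least 1 of the 6 fits that left out an array, 93 of them without untreated 2 and 79 without untreated 3, and in none of the 144 did the fold change move by more than 1.5 times. Each slide held arrays of 1 group only, so the slide block cannot separate slide from treatment. The other probe of Stard4, Odf2, Pfkfb3, Mylk and Rrm2 did not go the way of the probe given. Cox6b1 had 3 tested probes, and only 1 of the others went the way of the probe given. Under the normexp correction the fold changes of 38 of the 144 genes moved by more than 1.5 times, Il1b to 0.46 among them.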

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

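Every alternative in this part was planned, and only B2m was named after its value was seen. The count of 8670 changed probes stayed within 1.5 times under each scaling, with no filter, with a filter on all 6 arrays, with outlier spots kept, with trended and robust moderation, with the replicate block and with the slide as a random block (7036). With arrays of 1 group only on each slide, the slide block cannot separate slide from treatment. Array weights gave 14387 probes, 2937 genes higher and 5049 lower. A 2-fold minimum, which only removes genes, left 2104 probes, 163 genes higher and 888 lower, and at an unadjusted p it left 2250, 178 and 950. Genes higher moved from 1598 to 2756 with median centring and to 864 with no filter. With the replicate number as a block they numbered 768, which leaves fewer degrees of freedom. The labels do not say whether the numbers pair the samples. Deviations of same-numbered arrays from their group means correlated at −0.087, −0.028 and −0.024, and those of other-numbered arrays at −0.063 to 0.105. With 3 arrays per group and slides that differ by group, this cannot settle whether the samples were paired. Genes lower moved from 3209 to 1766 with quantile normalization, 1783 in the authors' table and 1856 with median centring, because these scalings remove the median shift. No list passed camera in the alternatives run, except 1 with the mean of a gene's probes; fry called 10.

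Leaving out 1 array gave 1881 to 8766 probes, 134 to 1725 genes higher and 820 to 3295 lower. The lowest counts came without untreated 2; without untreated 3 there were 2377 probes and without exosome 1 there were 3461. No list passed camera in these 6 fits.

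Signs turned for 5 named genes, 4 of which missed the test in the first place. Cyp17a1 was 0.20 with quantile normalization and 0.20 in the authors' table. Prm2 was 0.015 and 0.012 and Tex101 0.014 and 0.013 in the same alternatives. Ccl20 was −0.52 with array weights. B2m was 0.048 with median centring, and with 1 array left out it ranged from −0.32 to 0.0025. The cause was not tested for array weights, no filter, the mean of a gene's probes or the turned signs. Signal over background limits the dim genes, since 9542 of 10981 genes were above background on all arrays, where 1572 rose and 2628 fell.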

Other observations

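The gene families, the comparisons of probes and all explanations in this part were tested only after the results were seen. Of 40 families read from gene symbols 2 passed camera, and 1 of them was the rat major histocompatibility complex, RT1, whose class I molecules display peptides from inside the cell. Of 29 RT1 genes tested, all above background on all arrays, 22 fell and 0 rose, and under quantile normalization 17 fell and 0 rose. Class I genes had a median change of −0.69 (18 of 23 fell, 13 of them in all 5 scalings), and class II genes one of −0.63 (4 of 6 fell), or −0.60 and −0.31 under quantile normalization, where 0 of the class II genes passed the test. RT1-N3, RT1-CE2, RT1-CE4 and RT1-CE11 fell by 1.23 (SE 0.24), 1.05 (SE 0.17), 1.03 (SE 0.15) and 0.94 (SE 0.12), and the classical class I gene RT1-A2 by 0.77 (SE 0.15). RT1-A1 had a change of −0.30 ± 0.11 (adjusted p = 0.070), although its other probe fell past the test (−0.54, adjusted p = 0.020), and RT1-T24-4 one of 0.18 ± 0.12 (adjusted p = 0.283). Tap1 and Tapbp, which load peptides onto class I, fell by 1.19 (SE 0.19) and 0.83 (SE 0.21), while B2m, the shared light chain, had a change of −0.18 ± 0.18 (adjusted p = 0.434). Tapbp missed the test with median centring and in the fits without untreated 2, untreated 3, exosome 1 and exosome 3. Camera gave the RT1 family an adjusted p of 0.000395, which was lost with an estimated correlation (p = 0.053, adjusted p = 0.714). The number of RT1 genes that fell was 5 without untreated 2, 7 without untreated 3 and 13 without exosome 1, and since copies of these genes are nearly identical, their probes may read each other's transcripts, so that the count of 22 is uncertain.

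Olfactory receptor genes, which serve odour detection in the nose, were the other family past camera. Of 295 tested, 2 rose and 119 fell, with a median of −0.70, and under quantile normalization 14 rose and 68 fell, with a median of −0.29. Of the 295, 142 were above background on all arrays, and with a filter on all 6 arrays 61 fell and 1 rose. With 37 genes that were above background in 1 group only set to their bound, the median was −0.68. More of the family fell than rose in all 5 scalings. The genes were dim, and of all tested probes in the second and the third dimmest of 10 signal bins 38.5% and 39.8% fell, with medians of −0.58 and −0.49, so that the share of the family that fell was near that of other dim probes. Camera gave adjusted p = 1.26e-04, lost with an estimated correlation (p = 0.273, adjusted p = 0.714). Without untreated 2 there were 58 that fell, and without untreated 3 there were 64. Of the 40 families, 8 had an unadjusted p below 0.05, and with an estimated correlation 0 passed.

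If the fall of RT1 class I genes came only from fewer macrophages, which express class I strongly, macrophage markers should fall as far, and their median of −0.22 over 25 markers (95% interval −0.45 to 0.05) lay above the class I interval of −0.76 to −0.56. The markers went both ways, though, and 4 had changes below the class I median. These were Cd68 (−2.34, adjusted p = 0.308), Cd74 (−1.10), C1qc (−0.82) and Cybb (−0.79), so that a smaller part played by macrophages is not excluded. Cx3cr1, outside the list, also fell further (−1.94). It was named because its fall was among the largest, so it cannot count as evidence here. No marker stood in another of the 27 lists, and how many of them Leydig cells also express cannot be read from mixed RNA. Probe-specific differences between slides stay open, although 5 of 5 second probes of class I genes went the way of the first, because such probes can read the same transcripts. Another RT1 haplotype in the treated cells stays open too: 0 RT1 genes rose past the test, but the probes may match 1 haplotype only. A lower class I expression after contact with Sertoli cell exosomes is a hypothesis that these arrays cannot tell apart from either.

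Probes of 1 gene moved apart more than noise allows. Over 1490 genes with 2 tested probes, the fold changes of the pair correlated at r = 0.0017 (95% interval −0.053 to 0.056). Over 230 genes with a pair of bright probes, they correlated at r = 0.118 (95% interval −0.015 to 0.250), across genes, which are not independent replicates. For these bright pairs the error of the fit predicts r = 0.874 if both measured 1 change. Measurement noise as estimated within the groups is thus too small. Differences between slides that act on single probes may be the source. For exosome 3, alone on its slide, the contrast with the other exosome arrays correlated at r = 0.211 between the probes of the bright pairs. The same contrast gave 0.157 to 0.305 for the untreated arrays, which shared 1 slide. For exosome 1 and exosome 2 it gave −0.0028 and 0.038, but their contrasts include exosome 3. With 1 array alone on a slide, and 1 group per slide, these values decide nothing. Transcript forms that respond differently may also be a source, and bright pairs designed to 1 accession gave r = 0.103 for the fold changes, which leaves forms under 1 accession open. Over the 230 bright pairs the signal levels correlated with a Spearman rho of 0.571, and over the 1490 pairs with one of 0.341.

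The fall of dim probes cannot come from 1 scaling factor per array alone, which moves all probes alike, whereas the brightest of 10 signal bins lay 0.69 above the dimmest. Signal that does not come from the named transcript may play a part, but the control probes with no rat target cannot decide it. Only 3 of 22 were above background on at least 3 arrays, with a median of −0.57 and a range of −0.61 to 0.21. The 2 that fell were above background on 3 and 4 arrays, and the 1 above it on all 6 rose by 0.21. A fall of weakly expressed transcripts may be the cause as well: 5823 rat probes of the same signal had a median of −0.56. So few control probes, which moved both ways, cannot separate these explanations.

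Groups of 3 against 3 make 10 splits, too few for a share under 0.05. The real split gave 8670 probes, 1598 genes higher and 3209 lower, and 1 of the 10 splits, the real one, gave counts as large. The highest of the other splits was 0 for each. Those splits mix the groups on both sides, so any difference between the groups, slide included, widens their spread and lowers their counts. The comparison therefore cannot tell treatment from slide. For gene lists the real split gave 0 and the highest other split gave 3. That 10 of the 10 splits gave a number as large follows from the count of 0 and decides nothing.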
